A study of Mus musculus with 2 samples.

How the data were processed

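Gene expression was measured in dorsal skin of newborn mice (postnatal day 0, C57BL/6J background) that were wild type or lacked Sdr9c7. Each genotype was represented by 1 array, and per the series' design text each array received equal amounts of total RNA from 5 animals. The sample labels name the tissue as skin, dissected from the back, whereas the design text calls it epidermis. The RNA is treated here as whole skin, because transcripts of muscle, fat and dermis were well above background. Per the labels' protocols, the input to each 1-colour hybridisation was 200 ng of total RNA, labelled with the dye Cy3. Both arrays lay on the same slide, so slide and scan did not separate the genotypes. The array itself, with its labelling and hybridisation, was 1 per genotype and cannot be told apart from genotype.

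The authors' scanner files hold, per the file headers, the intensity of each of 44397 spots after extraction with Agilent Feature Extraction 11.5.1.1, which subtracted the background and corrected spatial trends within each array. Per the file headers, they also hold the raw mean intensity of each spot, its local background, the SD of its pixels, and flags for spots that were saturated, non-uniform, outliers or well above background. That last flag marks a spot whose signal exceeded a set multiple of the background's SD. The deposited series matrix holds a ratio per spot. Set against the scanner files, it was the processed intensity divided by 1 constant per array, 1906 for the wild type and 2080 for the knockout, on a linear scale with no centring of genes and with the genotypes not set against each other. The median ratio in the series matrix was 0.0855 for the wild type and 0.0840 for the knockout. The step that made these values is not given in the sources used here.

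The processed intensity was taken to log2, control spots and 192 spots marked as outliers on either array were left out, and spots of the same probe were averaged. Each array was then scaled by subtracting the 75th percentile over 39417 probes. Signals below are relative to that percentile, so that 1 equals it. A gene's value was the mean over its probes that were well above background and unsaturated on both arrays, and 22719 gene names were measured in this way. A further 1088 names had probes well above background on only 1 array. For these, the brighter array was set against the higher of the dim probe's own signal and the lowest signal among well-above-background probes on the dim array, and the result is given as "at least". Such lower limits carry no order among themselves.

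Of the probes, 28325 were named through their RefSeq accession, 2204 through a current symbol and 174 through a synonym, using a RefSeq gene table of assembly GRCm38.p6. The other 8714 kept the name in the scanner files. Probe coordinates in those files are on mm9, a different build, so the gene table served only for names and for finding which genes neighbour Sdr9c7.

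Without replicate arrays no test was run and no p-value is given. Differences are described against a 2-fold threshold and against technical spread. Among 320 probes with at least 8 usable spots, the SD of the log2 difference between spots had a median of 0.06, and 0.12 among the dimmest of them. Among 5155 genes with at least 2 measured probes outside the damaged block given below, the pooled SD between probes of a gene was 0.23. These values cover spot and probe error, not differences between animals, litters or dissections. The number of arrays limits the precision of every value.

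Gene lists were compared with 10000 random lists of the same size, matched on mean signal in 20 bins. A list is said to stand apart when its median log2 difference lay below the 2.5th or above the 97.5th percentile of those lists, which is a description of these 2 arrays and not a test. Genes of a list are regulated together and random lists are not, so standing apart is common. There were 41 ranked lists, 24 of pathways and 17 of cell type markers, and the Y-linked genes with Xist were reported by gene.

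The ranked lists, the thresholds, the scaling, most alternative settings and the rule for naming genes were fixed before the data were examined. The rule took Sdr9c7, the 12 largest and 12 smallest differences among measured genes at least 2-fold apart whose probes all differed at least 1.5-fold the same way, the 4 largest lower limits in each direction, up to 4 measured members of each list (2 at each end) and the genes within 500 kb of Sdr9c7. Clone and predicted names were not eligible. Lce1b, Sprr1a, Sprr2g, Sprr2i, Fosb, Fosl1, Ckm and Eif2s3y are named in the results outside this rule and were picked after their values were seen, as were the further genes of the closing section. A few genes that the rule names are not reported here. A search for damaged areas of the slide, with its limits and margin, was added after the data were seen. So were the subfamilies, the rule for when a value counts as changed under an alternative, and the repeat of the naming rule without the damaged areas. It marked spots whose 12 nearest detected spots had a median difference of over 1.5-fold, and took the area around the largest cluster with a margin of 2 rows and 1 column. It also marked bands of rows in which the raw log2 ratio of dim spots had an SD over 0.2 in a window of 21 rows.

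The procedure was tested on simulated arrays of the same 22719 genes, in which 50 genes at each of 4 folds and a list of 20 genes differed between knockout and wild type, with a noise SD of 0.12 on the log2 scale. Of 50 genes simulated at 3-fold, 100% passed the 2-fold threshold with the right sign, as did 100% of 50 at 4-fold and 100% of 50 at 8-fold, against 0% of 50 at 1.5-fold. None of 22499 unchanged genes passed, which follows from that noise SD. It is smaller than the pooled SD between probes, so this run checked that the code recovers what was put in and not how often real noise passes the threshold. Among 200 unshifted lists, 6.00% stood apart, and the list shifted 1.5-fold reached percentile 100. Of a simulated 8-fold loss over 158 spots, 100% was found, inside a box of 278 spots, and without such a loss no spot was marked. Lower limits were not simulated.

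The alternatives were normexp background correction of the raw signals (offset 50), scaling to the median of detected probes, quantile and loess normalization, the authors' series matrix values, no filter and a stricter filter on dim probes (at least 4 times the median undetected probe), the single brightest probe per gene, thresholds of 1.5-fold and 3-fold, lower limits left out, overlapping list members left out, and gene families counted once. Leaving out the damaged block, with and without the bands, was chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and limma 3.58.1 in R 4.3.3 for normexp.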

Results

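The study set skin of newborn Sdr9c7 knockout mice against wild type skin. Sdr9c7 is a short-chain dehydrogenase of the differentiating epidermis that acts on the linoleate-containing acylceramides of the skin barrier, and the study's title places the enzyme in barrier formation. The question addressed by the arrays is which transcripts differ in skin without it. There was 1 array for each genotype, each from RNA of 5 pooled animals, so no difference below has a replicate check. On the wild type array 74.9% of probes were well above background, and 76.8% on the knockout array, with 0 saturated spots on either. Across the 22719 measured gene names the arrays had a Pearson r of 0.994, a correlation across genes, which are not independent replicates.

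Sdr9c7 itself was 6.78-fold lower in the knockout (log2 difference −2.76). Its relative signal was 0.324 in the wild type and 0.0479 in the knockout, and the probe remained well above background on both arrays. The array carried 1 probe for the gene, on chromosome 10 from 127348150 to 127348209 (mm9), with the sequence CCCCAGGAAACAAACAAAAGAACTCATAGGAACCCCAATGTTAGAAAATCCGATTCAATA. Which part of the gene was deleted is not given in the sources used here, nor was the probe placed within an exon or UTR, because the annotation used is on another build. The lower signal fits the labels, but a residual signal says nothing about protein. After normexp background correction the log2 difference was −2.05. The probe lay in one of the bands of scattering rows, so the gene has no value with the bands left out.

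Of 37 measured genes within 500 kb of Sdr9c7, 36 were within 2-fold, with a median log2 difference of 0.03. The exception was Il23a, a subunit of the cytokine interleukin-23, at 1.19, with a dim signal of 0.00873 in the wild type. The neighbouring retinol dehydrogenase genes of the same enzyme superfamily stood at 0.06 for Rdh1, 0.12 for Rdh9, −0.29 for Rdh19 and 0.56 for Rdh16f2. The lowest neighbour was Coq10a at −0.39.

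Most of the transcriptome was alike in the arrays: 91.6% of measured genes were within 1.5-fold, and 1.88% were at least 2-fold apart. At least 2-fold higher in the knockout were 253 genes, 120 of them measured on both arrays and 133 as lower limits, and 475 were lower, 308 measured and 167 as lower limits. Of these, 172 higher and 356 lower carried a current RefSeq symbol. Normexp correction left 39 higher and 111 lower genes, and leaving out lower limits gave the 120 and 308 just named. Loess normalization gave 303 higher and 383 lower, so the excess of lower genes depended in part on the scaling.

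Part of these differences lay in identifiable areas of the slide. In rows 496 to 515 and columns 8 to 15 of the array, 34 of 95 detected spots were at least 2-fold higher in the knockout, and 7 of the 12 largest differences lay there. These were Crebbp (log2 difference 6.10), Iscu (4.36), Sdhaf4 (3.52), Oplah (3.23), Erp27 (3.04), Cabp5 (2.63) and Dpf2 (2.42). Of 13 probes printed at 10 positions with a spot in this block, 6 read lower there than elsewhere on the wild type array by over 3 SD, and 0 of the 7 in its inner, marked area were off by as much on the knockout array. The Sox9 probe read 51.1 inside it and 1496 on average at its other 9 positions on the wild type array, against 1769 and 1849 on the knockout array. The differences of those 7 genes are therefore not treated as expression differences. In rows 92 to 153 and 429 to 475, dim spots scattered more between the arrays than elsewhere, which is how these bands were defined. Leaving out block and bands left 107 higher and 249 lower genes.

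**Figure D1:**
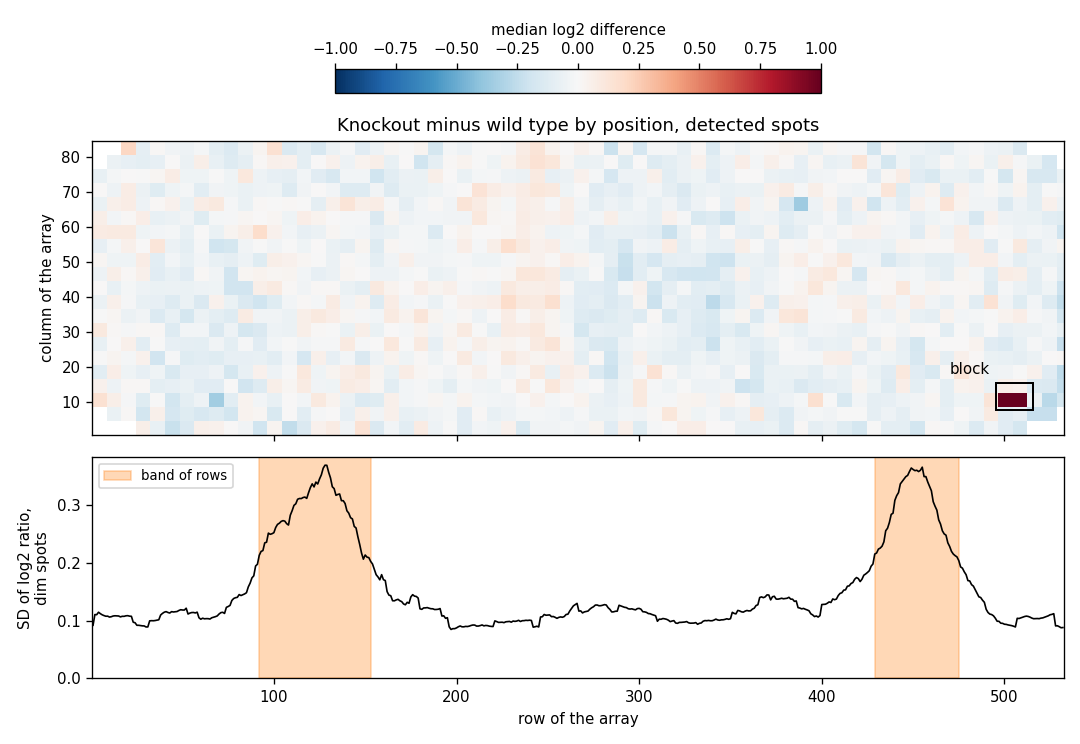
Position of differences on the slide. The upper panel shows the median log2 difference (knockout minus wild type) of detected spots in tiles of 8 rows by 4 columns, blank where a tile has fewer than 6 such spots, without column 85, and with colours ending at 1 in either direction, and the outlined block spans rows 496 to 515. The lower panel shows the SD of the raw log2 ratio of dim spots in a window of 21 rows, with the bands at rows 92 to 153 and 429 to 475 shaded.

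Outside the block, the largest higher values belonged to Lsmem1 (8.14-fold), Arc (8.11-fold), V1ra8 (5.79-fold), Sprr2e (5.45-fold) and Tctex1d4 (5.25-fold). Arc is an immediate early gene known from neurons, and Sprr2e encodes a small proline-rich protein of the cornified envelope. V1ra8 and Sprr2e lay in the bands described above, and V1ra8 and Tctex1d4 were dim, with wild type signals of 0.00627 and 0.00715 close to the lowest taken as well above background (0.00563). With block and bands left out, a set chosen after the values were seen, the 12 largest were Lsmem1, Arc, Tctex1d4, Ereg, an epidermal growth factor receptor ligand (3.60-fold), Sprr1b (3.39-fold), Fos, a subunit of the AP-1 transcription factor (3.37-fold), and Onecut2, Ahsg, Grm6, Hoxc11, Hand2 and Sprr2j-ps. These last 6 were also dim in both arrays, with relative signals under 0.1.

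The lowest values in the knockout, after that of Irf4 at −3.81 on the log2 scale (14.1-fold), were those of the olfactory receptor genes Olfr703 (−3.45) and Olfr1466 (−3.03), then Ccdc73 (8.02-fold) and Sdr9c7. Irf4, a transcription factor of lymphocytes, dendritic cells and melanocytes, had 1 probe, which read 0.833 in the wild type and 0.0593 in the knockout. Next came Phax (−2.71), Olfr424 (−2.63), Itih4 (−2.46), Pck1 (−2.30), Pvalb (−2.26), Adhfe1 (−2.25) and Spatc1 (−2.08). Of these 12 genes, 7 lay in the bands of scattering rows: Irf4, Olfr703, Ccdc73, Sdr9c7, Olfr424, Adhfe1 and Spatc1. Pck1, the phosphoenolpyruvate carboxykinase of glyceroneogenesis and gluconeogenesis, was 4.92-fold lower, from a relative signal of 0.990 to 0.201. Pvalb encodes parvalbumin, a calcium buffer of fast muscle fibres, and its 2 probes gave −2.23 and −2.28. The Ccdc73 spot had uneven pixels on the wild type array, with a pixel SD of 0.567 of its mean against a median of 0.163 outside the block, and the second probe of the gene was not above background on either array. Pixels were also uneven for Adhfe1 and Spatc1 (0.321 and 0.264, wild type), Olfr1466 (0.296, knockout) and Phax (0.274 and 0.266). Olfr1466, Phax and 1 of the 2 Pvalb probes lay in column 85, at the edge of the array, where the 12 other detected spots within 8 rows of Olfr1466 had a median of −0.38 and the 10 within 8 rows of Phax −0.23, against −0.07 for the whole column. The values of Olfr1466 and Phax are therefore uncertain. With block and bands left out, Cyp2e1 (3.81-fold), Rpl3l (3.40-fold), Cfd (3.38-fold) and the hair keratin-associated gene Krtap3-2 (3.21-fold) were among the 12 lowest, with H2-T3, Ces1f and Chrna9. The largest lower limits were Olfr176, at least 8.61-fold higher, Ankrd36, at least 8.24-fold, Hapln1, at least 7.61-fold and inside the block, and Gdf2, at least 6.64-fold. In the other direction they were Vmn1r234, at least 11.8-fold lower, Olfr1032, at least 9.69-fold, Pate9, at least 7.21-fold, and Svs4, at least 7.03-fold. Except for Hapln1 and Gdf2, these lay in the bands.

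**Figure D2:**
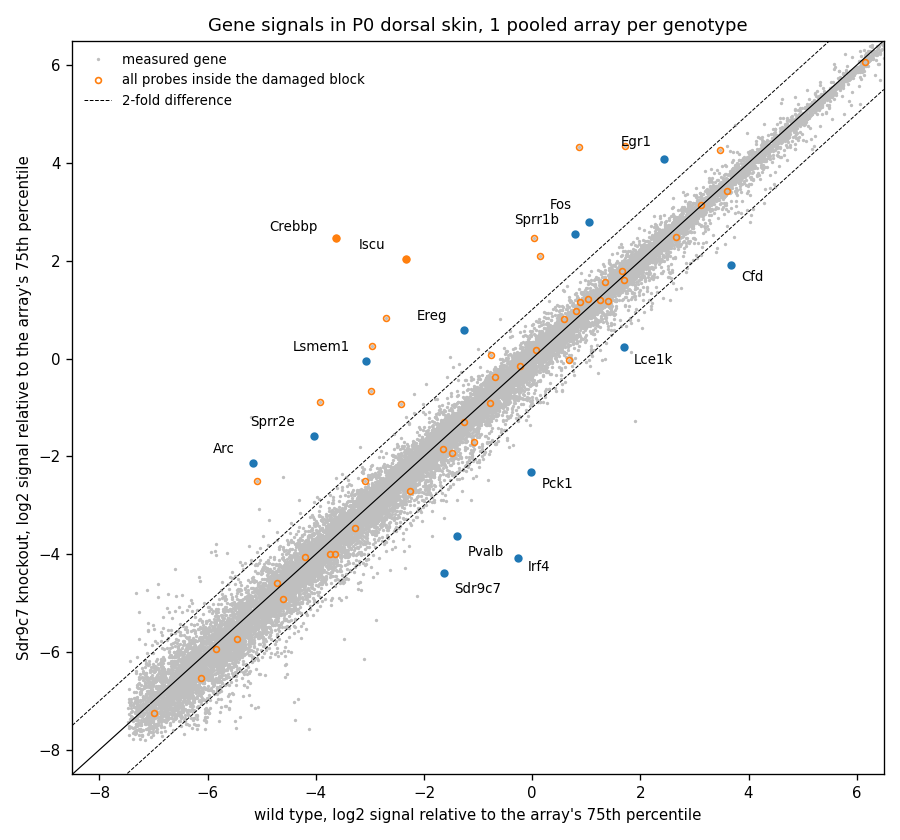
Relative signal of each measured gene in the wild type (x axis) and the Sdr9c7 knockout (y axis), both on a log2 scale against the array's 75th percentile, with 1 pooled array per genotype. Dashed lines mark a 2-fold difference, and orange circles are genes with all probes in the damaged block, such as Crebbp at 6.10, while Sdr9c7 lies at −2.76 and Irf4 at −3.81.

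Among transcripts of the cornified envelope, the protein shell of the outermost cells, families went apart. The 14 measured Lce1 genes, which encode late cornified envelope proteins, were all lower in the knockout, from −0.45 for Lce1b to −1.46 for Lce1k, with a median of −0.85. Lce1k went from a relative signal of 3.24 to 1.18 (2.75-fold lower) and Lce1h from 6.76 to 2.71. The 5 measured Lce3 genes were slightly higher, from 0.20 to 0.31, with Lce3e highest at 0.31 and Lce3c at 0.28. Both directions held under every scaling tried. Those scalings moved the median over all genes by only about 0.04 or less, so they could hardly have reversed either direction. The Lce3 values were about as large as the pooled SD between probes of the same gene (0.23). The late cornified envelope list as a whole had a median of −0.67 over 21 members (percentile 0), 4 of them at least 2-fold lower. The division by subfamily was chosen after the values were seen, and probes of these near-identical paralogs can share signal.

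The small proline-rich proteins, which crosslink the envelope and are induced when the barrier is stressed, had a median of 0.43 over 10 measured members (percentile 100). At least 2-fold higher were 4 of them, Sprr2e, Sprr1b (3.38-fold), Sprr2j-ps (3.14-fold) and Sprr2g (2.04-fold), and Sprr2i was at least 5.80-fold higher. Sprr2k was 2.28-fold lower and Sprr4 1.63-fold lower. The Sprr2k probe lay in a band of scattering rows and was dim, at 0.0151 in the wild type and 0.00665 in the knockout. Among the higher genes, the Sprr2e probe also lay in a band. Sprr2j-ps was dim, at 0.0202 in the wild type and 0.0633 in the knockout, and Sprr2i had only a lower limit. With block and bands left out the median was 0.43 over 8 members (6 above 0, 2 below). Sprr1a, among the brightest of the list, was level at −0.02. Near-identical Sprr2 paralogs can share signal on the array. With no filter on dim probes the median was 0.20 over 15 members (9 above 0, 6 below).

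Other structural proteins and the acylceramide pathway did not stand apart. Of 26 measured genes of acylceramide and lipid envelope synthesis, the pathway in which Sdr9c7 acts, 26 were within 2-fold, with a median of −0.04 (percentile 36.4). The lowest were Degs2, a sphingolipid desaturase and hydroxylase, at −0.85 and the lipid transporter Abca12 at −0.30, and the highest were the ceramidase Acer1 at 0.29 and Sptlc2 at 0.26. The cornified envelope structural list had a median of −0.06 over 18 members (percentile 24.7), from Lelp1 at −0.80 and Tchhl1 at −0.49 to Tgm3 at 0.27 and Rptn, repetin, at 0.81. Spinous and early differentiation genes had a median of 0.03 over 14 members (percentile 94.1), with Krt2 at −0.69, Krt77 at −0.28, Skint5 at 0.21 and Dsg1b at 0.28. Junction genes had a median of −0.02 over 20 members (percentile 54.8), with the claudins Cldn3 and Cldn23 at −0.61 and −0.56, and Tjp1 and Dsg3 at 0.13 and 0.15. Periderm and simple keratins had a median of −0.08 over 7 members (percentile 36.2), from Krt23 at −0.68 and Krt19 at −0.41 to Krt13 at 0.03 and Krt4 at 0.71.

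Proteases and inhibitors of desquamation and filaggrin processing lay slightly lower, with a median of −0.16 over 17 measured members (percentile 0.310). Prss8 and Klk7 were at −0.33 and −0.27, while Klk11 and Casp14 were both at 0.22. Basal keratinocyte genes lay slightly higher, with a median of 0.11 over 12 members (percentile 99.7), from Trp63 at −0.09 and Itgb4 at −0.02 to Krt15 at 0.34 and Dst at 0.47, the last with a probe in the damaged block. Cell cycle genes had a median of 0.21 over 19 members (percentile 100), with 17 above 0, among them Cenpe and Aurka, both at 0.55, while Mcm5 was at −0.01 and Tyms at −0.02. None of the measured members of these 3 lists reached 2-fold, although 1 protease list member was at least 2-fold higher as a lower limit. With block and bands left out, the basal list no longer stood apart (median 0.05, percentile 93.1).

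Immediate early genes, which respond within minutes to growth factors and stress, formed the highest list, with a median of 0.54 over 16 members (percentile 100). Fos (3.32-fold), Egr1 (3.11-fold) and Fosb (2.93-fold) were among the 4 that were at least 2-fold higher. Fos went from a relative signal of 2.08 to 6.91, and Egr1 from 5.40 to 16.8. Egr2 and Egr3 were at −0.27 and −0.24. Stress and wound keratins and serpins had a median of 0.28 over 21 members (percentile 100), with Ereg (3.60-fold), Hbegf, another ligand of the epidermal growth factor receptor (2.64-fold), and the AP-1 subunit Fosl1 (2.16-fold) at least 2-fold higher. No keratin or serpin of the list was at least 2-fold higher. Krt6a, a keratin of wounded epidermis, was at −0.24 and Serpinb3d at −0.21. Heat shock genes had a median of 0.11 over 11 members (percentile 98.9), from Hspb1 at −0.17 and Bag3 at −0.07 to Hsph1 at 0.21 and Dnajb1 at 0.44, and did not stand apart after normexp correction (median 0.08, percentile 96.8).

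Inflammatory transcripts were mixed. Epidermal cytokines and chemokines had a median of −0.30 over 17 measured members (percentile 0.2), with Il1a, interleukin-1 alpha, 2.70-fold lower, Il6 1.56-fold lower, Cxcl1 1.65-fold higher and Tnf 2.27-fold higher, all of them dim. After normexp correction the list had a median of −0.14 (percentile 9.61). Antimicrobial peptides and alarmins did not stand apart (median 0.07 over 17 members, percentile 93.9). Defb6, a beta-defensin (2.38-fold), and Slpi, a secreted leukocyte protease inhibitor (2.22-fold), were higher, while Chil1 was at −0.77 and Camp at −0.51. The Defb6 probe lay in a band of scattering rows and was dim, at 0.0119 in the wild type and 0.0284 in the knockout. Interferon-stimulated genes had a median of 0.16 over 18 members (percentile 99.7) with none at 2-fold, from Irf7 at −0.43 to Oas2 at 0.59 and Usp18 at 0.85. With block and bands left out their median was 0.13 (percentile 97.1). Oxidative stress genes driven by NRF2 had a median of −0.05 over 19 members (percentile 30.6), from Hmox1 at −0.72 and Gpx2 at −0.39 to Ugt1a6a at 0.49 and Slc7a11 at 0.52.

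The list of the fasting, glucocorticoid and PPAR response, several of whose members are also expressed in muscle and fat, had a median of −0.32 over 19 members (percentile 0) and 17 below 0. The markers of those tissues were lower too, as given below. Pdk4, which restrains glucose oxidation, was 2.37-fold lower and Txnip 1.76-fold lower, whereas the glucocorticoid target Fkbp5 was at 0.26. Fatty acid synthesis and lipogenesis had a median of −0.17 over 24 members (percentile 0.630), with Fads3 at −0.42, Elovl5 at −0.38, Acly at 0.30 and Elovl6 at 0.68. It stood apart neither after normexp correction (−0.11, percentile 5.61) nor with the brightest probe per gene (−0.08, percentile 13.8). Cholesterol synthesis had a median of 0.06 over 22 members (percentile 96.4), with Insig1 at −0.35, Hsd17b7 at −0.21 and Sqle at 0.29. Retinoid metabolism had a median of −0.04 over 24 members (percentile 45.8), from Stra6 at −0.72 and Aldh1a3 at −0.69 to Crabp1 at 0.68 and Lrat at 0.69. Epoxide and vitamin lipid-mediator enzymes had a median of −0.01 over 15 members (percentile 53.8), with Ephx2 at −0.25, Ptgds at −0.22, Ptgs1 at 0.29 and Ephx3, an epoxide hydrolase of the same lipid pathway, at 0.31. Hypoxia genes had a median of −0.03 over 14 members (percentile 45.6), with Bnip3 at −0.51, Adm at −0.45, Hk2 at 0.57 and Ankrd37 at 1.26. Circadian clock genes had a median of −0.14 over 15 members (percentile 8.33), with Per2 2.48-fold lower, Nr1d1 1.84-fold lower, Npas2 at 0.43 and Ciart at 0.96.

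The 2 lowest list medians were those of skeletal muscle and adipocyte markers. Skeletal muscle markers had a median of −0.97 over 19 members (percentile 0). Of these, 18 were below 0 and 8 were at least 2-fold lower, among them Pvalb (4.78-fold), Actn3 (2.86-fold) and Ckm (2.35-fold). Myh3, the embryonic myosin, was at −0.54 and Myh2 at 0.18. Adipocyte markers had a median of −0.84 over 12 members (percentile 0), with 12 below 0, Cfd, the adipokine adipsin, 3.39-fold lower and Retn, resistin, 2.25-fold lower, whereas Fabp4 was at −0.34 and Pparg at −0.02. Brown adipocyte markers did not stand apart (median −0.05 over 7 members, percentile 38.1). Cox8b and Ppargc1a were both at −1.11, while Elovl3 was at 0.29 and Ucp1 at 0.39. Without members held by other lists the brown adipocyte median was −1.07 (percentile 0), and with block and bands left out it was −0.39 (percentile 1.55).

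Further lower lists were smooth muscle and pericyte markers (median −0.50 over 8 members, percentile 0) and hair follicle markers (median −0.42 over 22 members, percentile 0). The former ran from Cnn1 at −0.97 and Des at −0.90 to Cspg4 at 0.04 and Pdgfrb at 0.09. The latter ran from the keratins Krt72 at −0.91 and Krt31 at −0.87 to the transcription factors Sox9 at 0.17 and Lef1 at 0.20. Melanocyte markers had a median of −0.29 over 8 members (percentile 0.510), with Oca2 2.43-fold lower, Pmel at −0.45, Dct at −0.07 and Mitf at 0.11. Schwann cell and nerve markers had a median of −0.24 over 9 members (percentile 1.72), with Pmp22 at −0.46, Mbp at −0.11 and Sox10 at 0.01. Endothelial markers had a median of −0.21 over 11 members (percentile 1.66), with Egfl7 at −0.43, Lyve1 at −0.31, Flt1 at 0.21 and Prox1 at 0.48. The melanocyte list lost its place with block and bands left out (−0.21, percentile 2.92), and the Schwann cell list with the brightest probe per gene (−0.19, percentile 2.55).

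Higher cell type lists were erythroid cells (median 0.47 over 9 members, percentile 100), cartilage and bone (0.38 over 7 members, percentile 99.8) and mast cells (0.19 over 8 members, percentile 99.9). Erythroid values ran from Hbb-bh1 at −0.37 and Hba-a2 at 0.21 to Alas2, which starts haem synthesis, at 0.63 and Hbb-y at 0.82. Col2a1, the collagen of cartilage, was 2.19-fold higher and Ibsp 1.61-fold higher, while Acan was at −0.33 and Bglap at −0.39. The erythroid median was 0.31 after normexp correction and the mast cell median 0.30 with block and bands left out. Without a filter on dim probes the cartilage list had a median of 0.11 (percentile 89.2). Mast cell values ran from Tpsb2 at −0.19 and Mcpt4 at 0.13 to the histamine-forming enzyme Hdc at 0.76 and Ms4a2 at 0.84, and 1 further member was at least 2-fold lower as a lower limit.

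Dermal fibroblast markers did not stand apart, with a median of −0.06 over 14 members (percentile 38.8), from Eln, elastin, at −0.50 and Col1a1 at −0.20 to Pdgfra at 0.12 and Thy1 at 0.20. Sebaceous gland markers had a median of 0.03 over 8 members (percentile 75.4), with Mc5r at −0.50, Mgst1 at −0.32, Awat2 at 0.26 and Elovl3 at 0.29. Macrophage, dendritic and Langerhans cell markers had a median of 0.01 over 15 members (percentile 62.4), with Cd14 at −0.52, C1qa at −0.16, Adgre1 at 0.25 and H2-Aa at 0.31. Neutrophil markers had a median of −0.11 over 8 members (percentile 38.3), with Camp at −0.51, Cxcr2 at −0.27, Ltf at 0.17 and Mmp8 at 0.45. T cell markers had a median of 0.03 over 8 members (percentile 77.2), with Cd4 at −0.46, Cd3e at −0.21, Thy1 at 0.20 and Cd3g at 0.24. Liver and plasma transcripts, included as a sign of other tissue, had a median of 0.09 over 3 measured members (percentile 77.2), and 1 more at least 2-fold higher as a lower limit, with Apoa2 at −0.10, Alb at 0.09 and Serpina1a at 0.10.

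**Figure D3:**
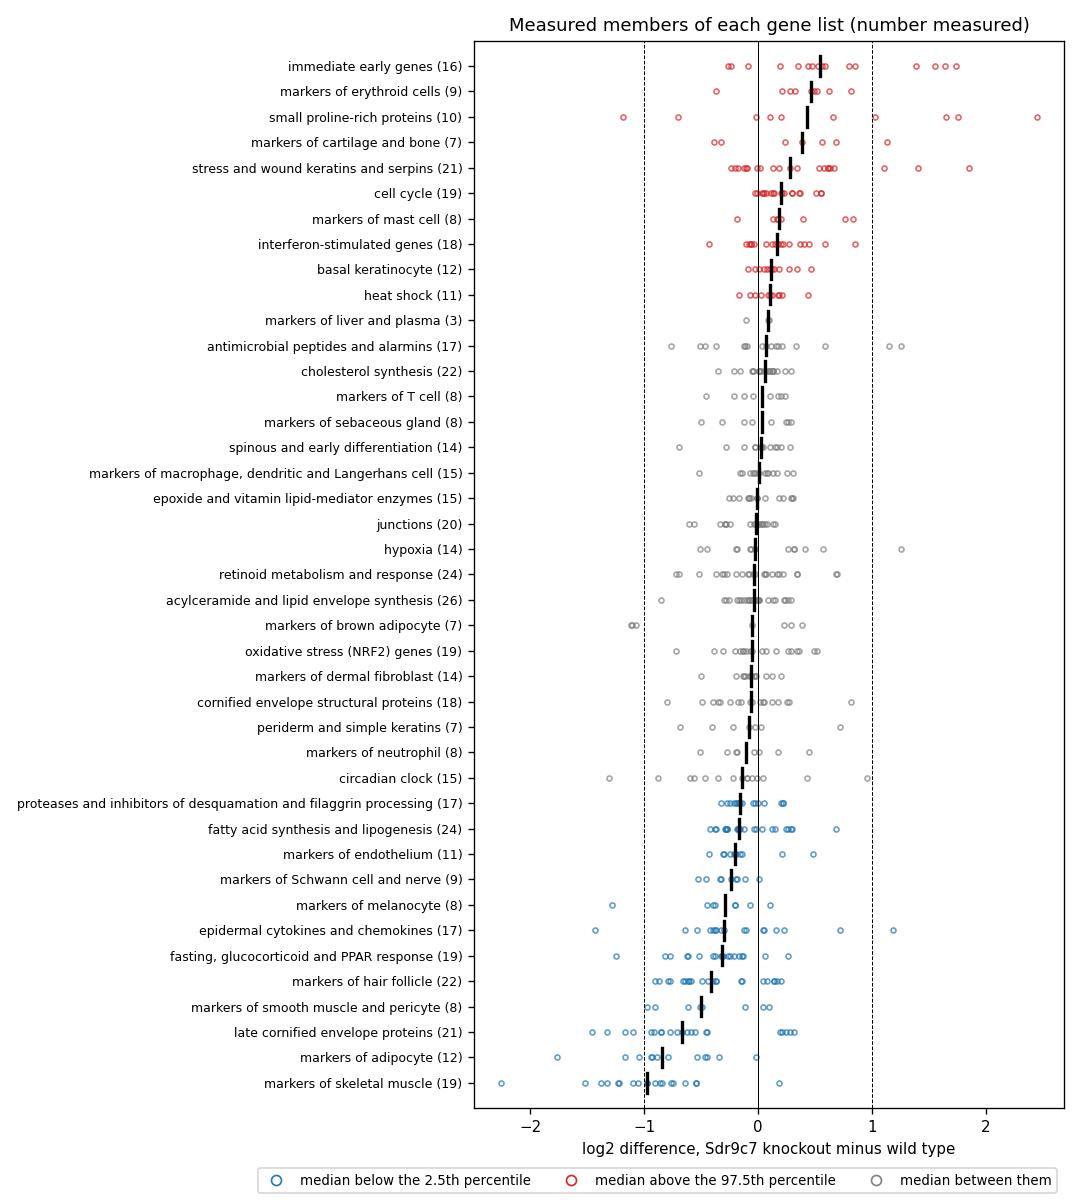
Log2 difference (Sdr9c7 knockout minus wild type) of every measured member of the 41 ranked gene lists, 1 circle per gene, with the list median as a black bar and the number measured in parentheses. Blue lists lie below and red lists above the percentile limits of matched random lists, from skeletal muscle at −0.97 to immediate early genes at 0.54.

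Of the 41 lists, 22 stood apart, 10 higher and 12 lower. The pools also differed in transcripts tied to sex. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were lower in the knockout at −1.02, −0.97, −0.93 and −0.36, and Xist, which silences an X chromosome in females, was higher at 1.09. Kdm5d was at −0.33 after normexp correction, and Ddx3y, whose probe lay in a band, had no value with the bands left out. The sexes of the pooled animals are not given in the sources used here. This difference stands beside every list above as a second way in which the pools were unlike.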

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

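The settings that leave out the block, with or without the bands, were chosen after seeing the data; the others were set beforehand. No paired analysis was possible because each genotype had 1 array and no test was run, and leaving out an array was not possible. Of 426 list values under the alternatives, 412 kept their side of the percentile limits, and 30 of 41 lists did so in every setting run. Of 2242 single gene values, 305 moved by at least the median SD between spots (0.06), 116 of them with normexp, 72 with quantile and 67 with loess normalization. The sign was kept in all settings by 210 of 230 genes, and no gene at least 2-fold apart changed sign. The median over all genes moved by no more than 0.04 between scalings.

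Counts of genes higher and lower were 39 and 111 with normexp, 814 and 978 with no filter on dim probes, 107 and 249 without block and bands, 799 and 1702 at 1.5-fold, 99 and 114 at 3-fold, and 120 and 308 without lower limits. The share of higher genes among them was 34.8% with the scaling used here, 39.3% with the detected median (273 and 422), 40.1% with quantile (278 and 415) and 44.2% with loess normalization (303 and 383). Of 24 genes named by size, 8 were at least 2-fold apart without block and bands, since those areas held the rest. Sdr9c7 was at −2.05 with normexp, whose offset compresses dim signals; without the bands it has no value, its probe lying in a band.

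With normexp, list medians were −0.14 for epidermal cytokines and chemokines, −0.11 for fatty acid synthesis and 0.0838 for heat shock, which no longer stood apart, and 0.0413 for spinous genes and 0.0770 for cholesterol synthesis, which then did. With the brightest probe per gene, cholesterol synthesis (0.0835) stood apart, and fatty acid synthesis (−0.0771) and Schwann cells (−0.19) did not. Without block and bands, interferon-stimulated genes (0.13), basal keratinocytes (0.0515) and melanocytes (−0.21) no longer stood apart and brown adipocytes (−0.39) did, as they did without shared members (−1.07). With no filter on dim probes, cartilage and bone (0.11) did not. The cause of these moves was not tested. Counting families once left too few members for a value in the small proline-rich and late cornified envelope lists. Signal over background limits the values of dim genes.

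Some lists stayed apart while their median moved over 1.5-fold. With no filter on dim probes, small proline-rich proteins were at 0.20; with normexp, erythroid cells were at 0.31 and cartilage and bone at 0.13; without block and bands, mast cells were at 0.30. Quantile normalization gave −0.11 for the proteases, −0.10 for fatty acid synthesis and 0.17 for heat shock, and loess −0.11 and 0.17 for the last 2; the brightest probe gave 0.0721 for basal keratinocytes.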

Other observations

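The tests reported here on the damaged block and on scaling were chosen only after the results they bear on had been seen, as was the present form of the test on dim spots, whereas those on fetal growth genes and on X-linked genes were set before their values were known. The test on dim spots had 2 earlier forms, both set aside because the bands had been defined with the same spots: the share of probes behind 2-fold lower limits that lay in the bands (65.6%, 3.44 times the share among dim spots), and the scatter of repeated probes in bands found from all spots (2.35 times on the knockout array).

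Gene families of the hair shaft and its sheath, picked out after their values were seen, were lower as well, and the keratins among them share members with the hair follicle list. Of 46 measured Krtap genes, which encode the proteins that crosslink hair keratins, 45 were lower in the knockout, with a median of −0.89, and 15 were at least 2-fold lower. Krtap3-2 (3.21-fold), Krtap7-1 (2.61-fold) and Krtap6-1 (2.40-fold) were among them. The 13 measured hair keratins had a median of −0.77, and the 7 keratins of the inner root sheath, which lines the hair canal, were all lower, with a median of −0.61. Krtap genes are near-identical in groups and their probes can share signal, so they count for fewer than 46 separate values.

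Other genes were also picked after their values were seen and form no fixed list. The 10 measured Mup genes, for major urinary proteins, were all lower, with a median of −0.96, and are so alike in sequence that their probes can share signal. C3 (2.07-fold), Trf (2.36-fold) and Lpin1, a phosphatidate phosphatase of fat storage (2.29-fold), were lower too, whereas Alb and Serpina1a of the liver and plasma list stood at 0.09 and 0.10. In muscle, Mstn, which restrains muscle growth, was 2.64-fold lower and Trim63, a ubiquitin ligase of muscle wasting, 2.28-fold lower. On the side of higher genes stood Dkk4, a Wnt inhibitor (2.94-fold), Hes5, a Notch target (2.70-fold), Ovol1, a transcription factor of epidermal differentiation (2.45-fold), and Tnfaip3, an inhibitor of NF-κB (2.27-fold).

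Large differences gathered in parts of the slide. A local loss of signal on the wild type array may account for those in the block: of 7 probes printed both in the marked area and elsewhere, 6 read lower there by over 3 SD of their other spots on the wild type array, with a median log2 shift of −2.89, while on the knockout array the shifts lay between −0.06 and 0.05. This test was run at first on the block with its margin, where 6 of 13 probes were lower, the median shift was −0.45 and the prediction was not met; it was then limited to the area marked before the margin was added, because none of the 6 probes of the margin was lower by over 3 SD. Scatter of dim spots may account for part of the differences in the bands: with bands found from the other probes only, 55 dim probes printed at 10 positions scattered 2.33 times as much inside as outside on the knockout array and 1.60 times on the wild type array. A biological explanation for a place on the slide was not tested.

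Muscle and fat transcripts were low together with hair, smooth muscle and melanocyte transcripts, most of which lie beneath the epidermis. Fibroblast markers there were level (−0.06), and mast cell (0.19), cartilage (0.38) and erythroid (0.47) markers were higher. The muscle median stayed at −0.93 or lower under 3 other scalings, so it did not depend on the choice among them. Those scalings moved the median over all genes by only about 0.04 or less. They could hardly have removed a difference of this size, so the test says little more about scaling. A smaller share of muscle in the knockout pool stays open: the spread of its markers (SD 0.49) had been set against that between probes of the same gene (0.23), but this was set aside, since lists that did not stand apart spread more than probes as well, such as retinoid metabolism (0.36). An earlier developmental stage of the knockout pool would likely raise fetal growth genes. These had a median of −0.20 over 17 genes (percentile 0.1), with H19 at −0.72 and Igf2 at −0.62. Of the 17, 5 were above 0, the highest being Gpc3 at 0.47, with Lin28b at 0.28 and Hmga2 at 0.14 among the others. Several of these genes are also expressed in fetal muscle, and muscle markers were low here, so the test cannot decide on the stage. An earlier stage therefore stays open. An effect of the genotype, and a difference in the depth of dissection, remain open as well and were not tested.

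The lower Y-linked transcripts and higher Xist could come from fewer males in the knockout pool. The Y-linked genes were lower and Xist higher in every setting in which they had a value. X-linked genes that escape silencing had a median of 0.0906 over 8 genes (percentile 91.1), from Jpx at 0.49 to Car5b at −0.49. With 5 of the 8 above 0, that list by itself cannot decide the matter. Its result takes nothing from the Y-linked and Xist values, which moved in opposite directions, as fewer males in the knockout pool would give. Kdm5c, another such gene, was left out of that list because its value, 1.04, had already been seen; 1 of its 2 probes lies in the damaged block, and the probes gave 1.79 and 0.30. Whether sex contributes to the other differences cannot be told apart from genotype here, since each genotype was a single pool.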
